A study of Mus musculus with 6 samples.

How the data were processed

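RNA-seq was run on 6 libraries of sorted brain endothelial cells from mice carrying Df(h22q11)/+, a heterozygous deletion that models human 22q11.2 deletion syndrome. Per the labels, mice aged 12 to 16 weeks ate base chow (untreated, 3 libraries) or chow with 0.5% bezafibrate (3 libraries) for 4 weeks. Each library is a pool of 3 brains from mice alike in sex, genotype and chow. Pools of separate animals are the replicates, so p-values measure the spread between pools. Untreated libraries are named F_1, F_2 and M_1 and bezafibrate libraries F_1, M_1 and M_2, where F is female and M is male. A shared name across the groups was not taken to pair them.

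Per the labels' protocols, perfused brains were dissociated with papain, collagenase and neutral protease, and live CD31-positive, CD45-negative, PDGFRb-negative cells were collected by FACS. This gate keeps endothelial cells and is meant to exclude leukocytes and pericytes. The labels name SMART-Seq HT for cDNA, Nextera XT for libraries and single-end reads of 75 bases. They state that reads were de-duplicated and mapped with Salmon, and the submitters' processing notes name GRCm38. The version of Salmon, the annotation, the use of strand and the normalisation of the table are not given in the sources used here.

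The deposited table holds FPKM (fragments per kilobase of transcript, scaled to library size) for 54532 genes, with gene IDs, positions, lengths and biotypes, as made by the authors. The column for the untreated male library carries another number than its title, and was assigned through the description of that sample. Gene names that a spreadsheet had turned into dates numbered 27, and 27 were restored from their gene IDs. Of the genes, 54409 were found in the GENCODE mouse annotation of GRCm38, 98.3% of them with the same start and end. Positions are those of the table.

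FPKM multiplied by gene length fell on whole multiples of a single step in each library, for 100% of the values at a tolerance of 0.01 reads. This gave 19110040, 18284412 and 20228619 summed reads in untreated F_1, F_2 and M_1, and 19070085, 18893195 and 16858130 in bezafibrate F_1, M_1 and M_2. The step also gives the library size by which the FPKM were scaled. Summed reads divided by that size, called the composition ratio here, differed between libraries, and what sets it is not given in the sources used here. Recovered reads served for depth, for lower bounds against a floor of 3 reads over the group at 0, and for an added limma-voom fit. Floors cover counting error only, and bootstrap intervals the spread between the genes of a list, so that neither covers the spread between animals.

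Analysis used log2(FPKM + 1). A log2 difference on this scale understates the change of low genes. Genes with FPKM of at least 1 in at least 3 libraries were kept, which left 11277, of which 10066 were protein-coding. Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, statmod 1.5.0 installed), two-sided, and p was adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. Treatment (bezafibrate minus untreated) had no covariate, since the labels say that the sexes were combined. Sex (male minus female) was fitted with treatment as a covariate, and the interaction in a fit with treatment, sex and their product. The interaction fit leaves 2 residual degrees of freedom and rests on a single library in 2 of its 4 cells. Exact permutation of a single gene cannot go below a two-sided p of 0.1 for 3 against 3.

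Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, which compares a list with the other genes measured. The 30 pathway and vessel-zone lists and the 9 cell type lists with at least 5 measured members were adjusted as separate families. Camera with an estimated correlation and fry were alternatives. The alternative fits counted for each list (24 or 23) use the preset correlation and leave these tests out. The pathway lists covered PPAR-alpha targets, fatty acid oxidation, respiratory complexes, mtDNA-encoded mRNAs, the mitochondrial ribosome, the TCA cycle, mitochondrial biogenesis and dynamics, glycolysis, junctions, blood-brain barrier transporters, caveolae, Wnt/beta-catenin, leukocyte adhesion, interferon, antigen presentation, the stress and antioxidant responses, sterol synthesis, angiogenesis, basement membrane, cell cycle, the 22q11.2 interval, the cytosolic ribosome and immediate early genes. Zone lists were arterial, capillary and venous. Cell type lists were endothelium, pericyte, smooth muscle, fibroblast, astrocyte, oligodendrocyte and its precursor, neuron, microglia, macrophage, lymphocyte and neutrophil, ependymal and choroid plexus, and erythrocyte. Within a list, genes were also counted as called when adjusted over the list alone.

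The groups, tests, lists, other settings to try and the rule for named genes were fixed before the data were examined. The rule takes protein-coding genes off the Y chromosome and other than Xist whose 3 untreated and 3 bezafibrate values do not overlap. Of these it takes, in each direction, the 12 with the largest change among those called, filled by smallest unadjusted p where fewer passed. It adds the 2 members of smallest unadjusted p in each pathway and zone list, 20 PPAR, barrier and adhesion genes, the 5 genes of smallest p in each direction for sex and the 3 of smallest p for the interaction. Other genes named, among them Gm27616, Gm11626, Akap12, Kdm6b, mt-Co1, Lamc1, Mobp, Ttr, Clic6, Trpv4, Smad6, Itga3, Wnt11, Cmpk2, Gbp7 and the pituitary hormones, were chosen after their values were seen. Single values of some genes are not reported here.

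The settings chosen then were pseudocounts of 0.1 and 5, other filters, rescaling to TPM, median-of-ratios and quantile scaling, autosomal protein-coding genes, eBayes without a trend or robust, array weights, sex as a covariate, the replicate name as a block, and each library left out. Added after seeing the data were limma-voom on recovered reads, the composition ratio as a covariate, removal of each library's gene length trend, a fit without untreated M_1 and bezafibrate F_1, and protein-coding genes alone. No library pair agreed within sampling noise (chi-square per gene of at least 26.8), so 6 samples were kept.

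The pipeline was tested on simulated data of 11008 genes for the treatment comparison, with 3 libraries a group. With 50 genes changed by each size, 2% were called at a log2 change of 0.5, 72% at 1, 98% at 2 and 100% at 3, besides 6 unchanged genes. The changed genes were drawn above a minimum mean value and were changed together. These rates therefore do not apply to low genes or to data in which few genes change. In 20 draws with nothing changed, any gene was called in 4 and any list in 1. Genes were drawn independently of each other, whereas the estimated correlation in the data was 0.50 for mtDNA-encoded mRNAs and 0.25 for immediate early genes. The rate of list calls in these draws therefore does not carry over to the data. A list made to shift by -0.5 was found at a median of -0.60 (camera adjusted p 5.15e-14). The read step was recovered in 100% of simulated libraries.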

Results

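Gene expression was measured by RNA-seq in CD31-positive endothelial cells sorted from the brains of Df(h22q11)/+ mice, which carry a deletion of the region orthologous to human 22q11.2. The comparison asked what bezafibrate, a fibrate that activates PPAR nuclear receptors, did to these cells after 4 weeks in the chow. The untreated group had 2 female libraries and 1 male library, and the bezafibrate group 1 female and 2 male libraries, each from 3 pooled brains. Wild-type mice were not analysed here. Depth was even, with 16858130 to 20228619 recovered reads per library and 11060 to 11387 genes at an FPKM of at least 1.

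The libraries were rich in endothelial transcripts. Slc2a1, the glucose transporter of the blood-brain barrier, stood at 4447 ± 1297 FPKM in untreated libraries (SD, n = 3), and the tight junction gene Cldn5 at 1183 ± 189.6. Of the cell type lists, fibroblast (3 genes), neuron (3), macrophage (1) and lymphocyte and neutrophil (0) had too few measured members for a test. Untreated M_1 and bezafibrate F_1 stood apart from the other libraries on the first principal component, which held 39.3% of the variance. Their scores were 30.3 and 24.4, against -14.1 and 1.62 in untreated F_1 and F_2 and -19.7 and -22.6 in bezafibrate M_1 and M_2. The composition ratio was 1.09 in untreated M_1 and 1.06 in bezafibrate F_1, and 0.950, 1.03, 0.889 and 0.897 in untreated F_1, untreated F_2, bezafibrate M_1 and bezafibrate M_2.

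**Figure D1:**
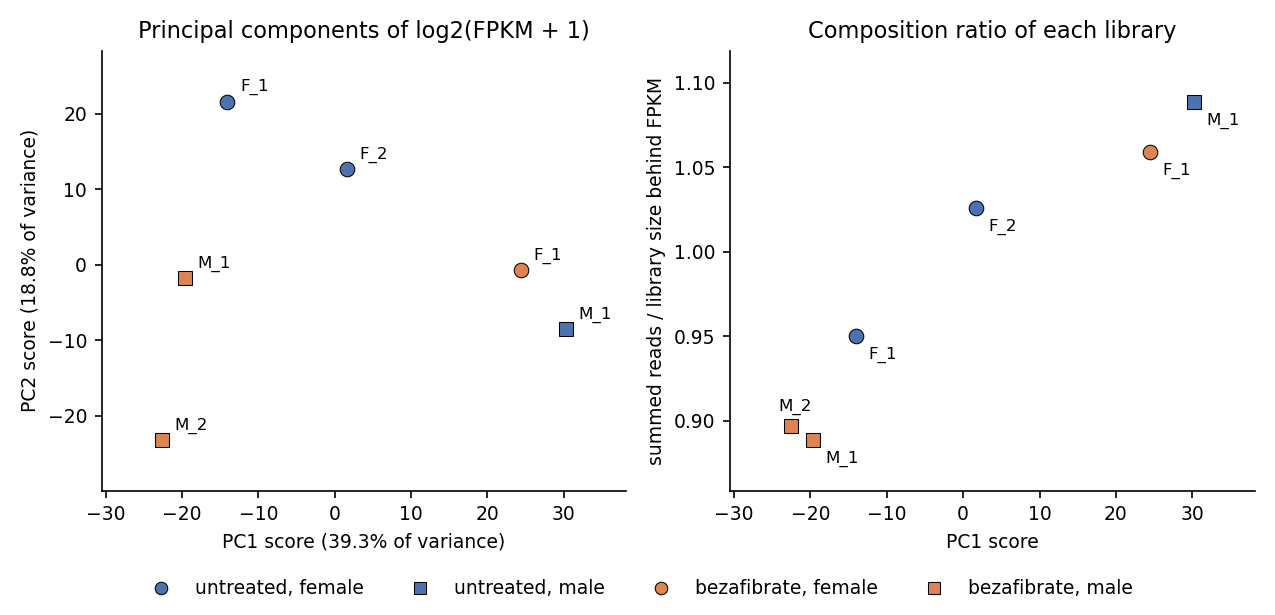
The left panel plots the scores of the 6 libraries on the first principal components of log2(FPKM + 1), and the right panel the composition ratio of each library against its score on the first component. Untreated M_1 and bezafibrate F_1, at scores of 30.3 and 24.4, have composition ratios of 1.09 and 1.06.

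Bezafibrate changed no protein-coding gene past the threshold. The single call among 11277 genes was Gm27616 (ENSMUSG00000098259), a predicted microRNA of 63 bases on chromosome 1 (162674158 to 162674220, minus strand), inside Prrc2c and outside its exons. It had 0 reads in each untreated library and 10, 14 and 8 in bezafibrate F_1, M_1 and M_2 (8.82, 10.5 and 6.76 FPKM), at least 10.4-fold higher against a floor of 3 reads over the untreated group (limma adjusted p = 0.00242). Its length is below the read length of 75 bases. Without any 1 of the bezafibrate libraries it no longer met the expression filter, and the count of calls was 0 without M_1, 0 without M_2 and 0 by limma-voom.

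Among 10066 protein-coding genes, limma called 0, with a smallest adjusted p of 0.962. At an unadjusted p under 0.05 there were 364 such genes, where 503 would be counted by chance. Over all genes 472 lay under 0.05 (237 higher, 235 lower, 564 by chance), and the groups did not overlap in 950 genes (484 higher, 466 lower), or 8.42%, against 10% by chance. The median SE of a log2 difference was 0.191, and the top-ranked gene would have needed a difference of 2.2 at that SE. Without bezafibrate F_1, limma called 3 other genes, each lower with bezafibrate: Akap12, Kdm6b and Tnfrsf10b, a death receptor for TRAIL, at -2.04 (adjusted p = 0.0467) against -1.56 (SE 0.384) with all libraries.

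The protein-coding genes ranked highest by the named-gene rule did not pass the threshold, and their values are given as measured. Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), a target and feedback inhibitor of Wnt/beta-catenin signalling, had 10.03 ± 1.13 FPKM in untreated and 17.3 ± 0.592 in bezafibrate libraries (SD, n = 3 each), a log2 difference of 0.74 (SE 0.133). Igfbp3, a carrier of insulin-like growth factors, had 58.2 ± 9.90 and 99.0 ± 14.0 FPKM. Cited4, a transcriptional co-activator, had 7.90 ± 1.01 and 15.5 ± 3.71. Ndufaf1, an assembly factor of respiratory complex I, had 2.24 ± 0.120 and 4.46 ± 0.964, and the retinoic acid receptor Rarg 14.3 ± 0.162 and 20.8 ± 1.31. The others with a positive difference were Miip, Gm4950, Chst14, Zswim1, Colca2, Ptcd2 and Fam181b, between 0.66 and 1.16, of which Fam181b shares 56.8% of its exon bases with the antisense gene Gm9934.

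On the other side, Pi4k2b (ENSMUSG00000029186, chromosome 5, 52741574 to 52769340), a phosphatidylinositol kinase, had 3.40 ± 0.105 FPKM in untreated and 1.68 ± 0.0962 in bezafibrate libraries, a log2 difference of -0.72 (SE 0.143). The homeobox gene Irx3 had 24.1 ± 1.54 and 11.1 ± 4.45 FPKM. Fosl2, a subunit of the AP-1 transcription factor, had 46.8 ± 6.90 and 23.5 ± 8.0, and the immediate early nuclear receptor Nr4a1 667 ± 164 and 355 ± 61.8. Mbp, which encodes myelin basic protein of oligodendrocytes, had 13.4 ± 1.79 and 8.88 ± 0.450. The remaining differences were Shld1 -0.59, Nsun6 -0.60, Phlda1 -0.68, Mapk6 -0.80, Prr29 -0.80 and Dusp5 -0.84. Phlda1 and Dusp5 share 33% and 22.1% of their exon bases with antisense genes.

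**Figure D2:**
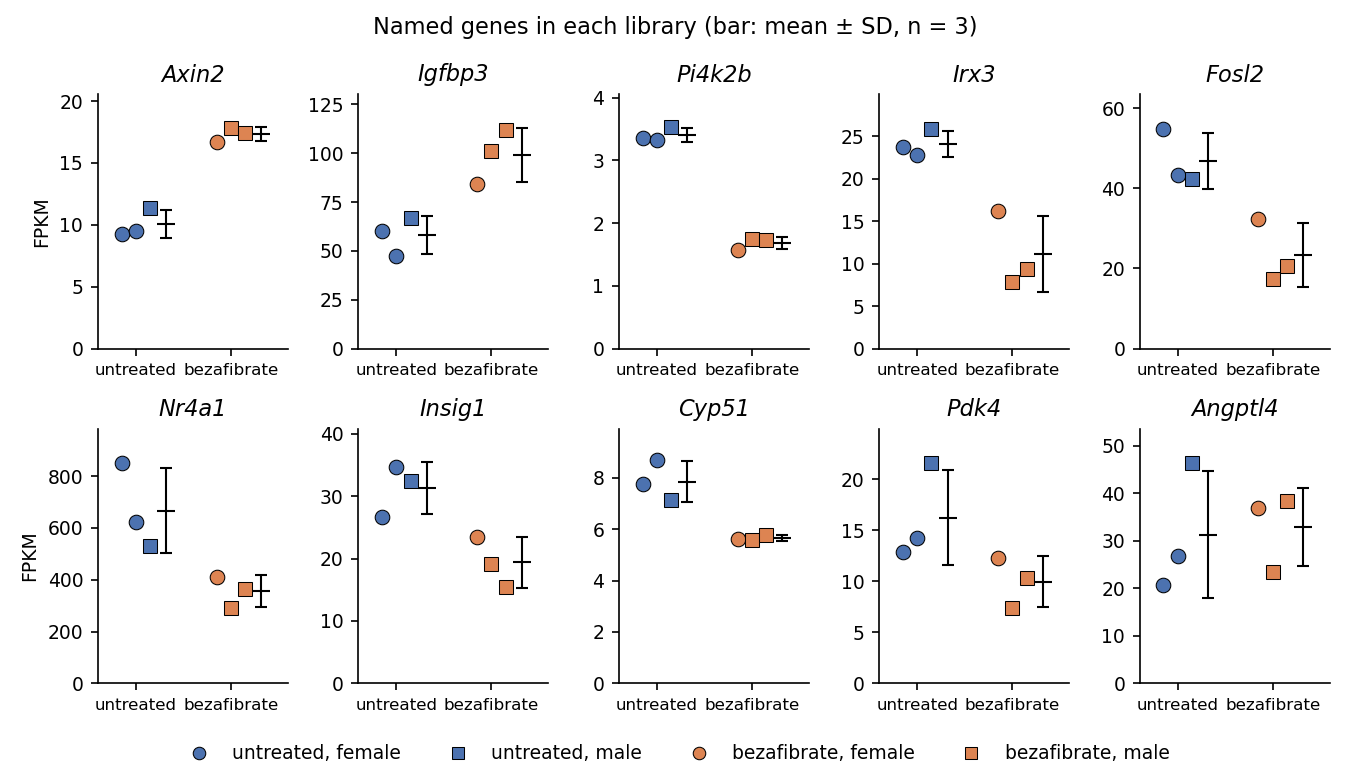
FPKM of 10 named genes in each library, by treatment (colour) and sex (symbol), with bars at the mean ± SD of 3 libraries. Axin2 lies between 9.29 and 11.3 in untreated and 16.7 and 17.9 in bezafibrate libraries, while the values of Angptl4 overlap.

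Canonical PPAR targets did not move as a group. Of 31 measured PPAR-alpha targets, 12 had a positive and 19 a negative difference, with a median of -0.06 (camera adjusted p = 0.293), and none was called over all genes or adjusted over the list alone. Pdk4, a kinase that restrains pyruvate oxidation, had 16.2 ± 4.66 FPKM in untreated and 9.97 ± 2.49 in bezafibrate libraries. Angptl4, an inhibitor of lipoprotein lipase, had 31.3 ± 13.4 and 32.9 ± 8.15, and the carnitine palmitoyltransferase Cpt1a 43.7 ± 3.59 and 39.8 ± 6.83. The lipid droplet gene Plin2 had 12.4 ± 1.03 and 13.4 ± 2.40. Slc25a20, the mitochondrial acylcarnitine carrier, had 7.07 ± 0.882 and 5.10 ± 0.491. The receptor Ppard had 26.7 ± 4.86 and 25.2 ± 3.33 FPKM, whereas Ppara (0.117 to 0.449), Pparg (0.0505 to 0.551) and the co-activator Ppargc1a (0.0817 to 0.528) lay below the filter in each library.

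Among 30 pathway and zone lists, 7 were called with camera at the preset correlation, 5 lower and 2 higher with bezafibrate. None was called with an estimated correlation (smallest adjusted p = 0.332) or by fry (smallest adjusted p = 0.180). Of 10 splits of the 6 libraries into 3 and 3, 3 called at least 7 lists, the real split among them, and another called 8. None of the members of these 7 lists was called, over all genes or adjusted over the list alone. Rescaling to TPM moved the median of all genes from -0.01 to 0.10, and quantile scaling called 5 lists, 3 higher and 2 lower. Each of the 7 medians kept its sign under the other scalings.

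Genes of sterol synthesis and uptake, targets of SREBP2, were lower with bezafibrate. The median of 21 measured genes was -0.36 (interquartile range -0.40 to -0.13), with 20 below 0 and 1 above, and 6 at an unadjusted p under 0.05 (camera adjusted p = 8.94e-07). With an estimated correlation the adjusted p = 0.332. Insig1, the endoplasmic reticulum anchor of the SREBP pathway, had 31.3 ± 4.18 FPKM in untreated and 19.4 ± 4.05 in bezafibrate libraries. Cyp51, which demethylates lanosterol, had 7.85 ± 0.785 and 5.66 ± 0.102. The mean log2 value of the list was 2.82, 2.96 and 2.83 in untreated F_1, F_2 and M_1, and 2.60, 2.62 and 2.48 in bezafibrate F_1, M_1 and M_2. In these libraries the oligodendrocyte and astrocyte markers were also lower, at medians of -0.19 and -0.18. The sterol list was called in the same direction in 24 of 24 alternative fits at the preset correlation, between -0.40 and -0.15. It was not called with an estimated correlation or by fry (adjusted p = 0.180).

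Immediate early and dissociation-induced genes were lower, with a median of -0.22 and 27 of 28 below 0 (camera adjusted p = 9.65e-06). With an estimated correlation the adjusted p = 0.657. Besides Nr4a1, the matricellular gene Cyr61 had 1591 ± 183.6 FPKM in untreated and 1087 ± 119 in bezafibrate libraries. The call held in 23 of 24 alternative fits and ended under quantile scaling (-0.04, adjusted p = 0.414). With a library left out the median ran from -0.23 to -0.14.

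The 13 mRNAs encoded by mtDNA were lower, at a median of -0.23 with 12 below 0 (camera adjusted p = 2.94e-04, and adjusted p = 0.657 with an estimated correlation). The oxidase subunit mt-Co1 had 7480 ± 878 FPKM in untreated and 6004 ± 254 in bezafibrate libraries, and mt-Nd5, of complex I, 940.3 ± 139.8 and 742 ± 24.4. The mtDNA share of all FPKM was 9.53%, 7.59% and 8.26% in untreated F_1, F_2 and M_1 and 7.08%, 7.54% and 8.0% in bezafibrate F_1, M_1 and M_2. The call held in 19 of 23 alternative fits and ended without untreated F_1 (-0.15, adjusted p = 0.277), under quantile scaling (-0.08, 0.186), with array weights (-0.16, 0.227) and without both untreated M_1 and bezafibrate F_1 (-0.16, 0.334).

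Nuclear genes of respiratory complex I and of the mitochondrial ribosome were higher. Of 37 complex I genes 27 lay above 0, with a median of 0.09 (camera adjusted p = 0.0183), and of 75 mitochondrial ribosome genes 50 did, also with a median of 0.09 (adjusted p = 0.00351). Both had an adjusted p = 0.657 with an estimated correlation. Ndufc1 and Ndufb9, of complex I, had 5.08 ± 0.636 and 8.91 ± 0.852 FPKM in untreated libraries and 7.35 ± 0.863 and 11.9 ± 1.76 in bezafibrate libraries, and the ribosomal gene Mrps21 17.0 ± 1.79 and 25.6 ± 2.43. The mean log2 value of complex I was 4.03, 3.96 and 4.24 in bezafibrate F_1, M_1 and M_2 against 3.93 to 4.01 in untreated libraries. That of the ribosome was 2.50 in untreated M_1 and 2.48 in bezafibrate F_1, the libraries that stood apart, and 2.59 and 2.60 in the other untreated and 2.72 and 2.81 in the other bezafibrate libraries. Without bezafibrate M_2 the medians were 0.01 (adjusted p = 0.784) for complex I and 0.06 (0.185) for the ribosome, and without untreated M_1 both were 0.06 (0.106 and 0.0849). Complex I was called in 18 and the ribosome in 19 of 24 alternative fits. Complex I calls also ended with array weights (0.04, adjusted p = 0.155), the replicate block, the composition ratio as a covariate and without both untreated M_1 and bezafibrate F_1 (0.12, 0.0824). Ribosome calls also ended with sex as a covariate (0.11, 0.0631), the replicate block and the composition ratio. Complexes II to IV (median 3.1e-04, adjusted p = 0.895), ATP synthase (-0.05, 0.668), fatty acid oxidation (-0.03, 0.312), the TCA cycle (0.01, 0.970), mitochondrial biogenesis (0.07, 0.141) and mitochondrial dynamics (-0.0014, 0.895) were not called. Tfam, which packages mtDNA, had 2.96 ± 0.831 and 2.98 ± 0.816 FPKM.

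**Figure D3:**
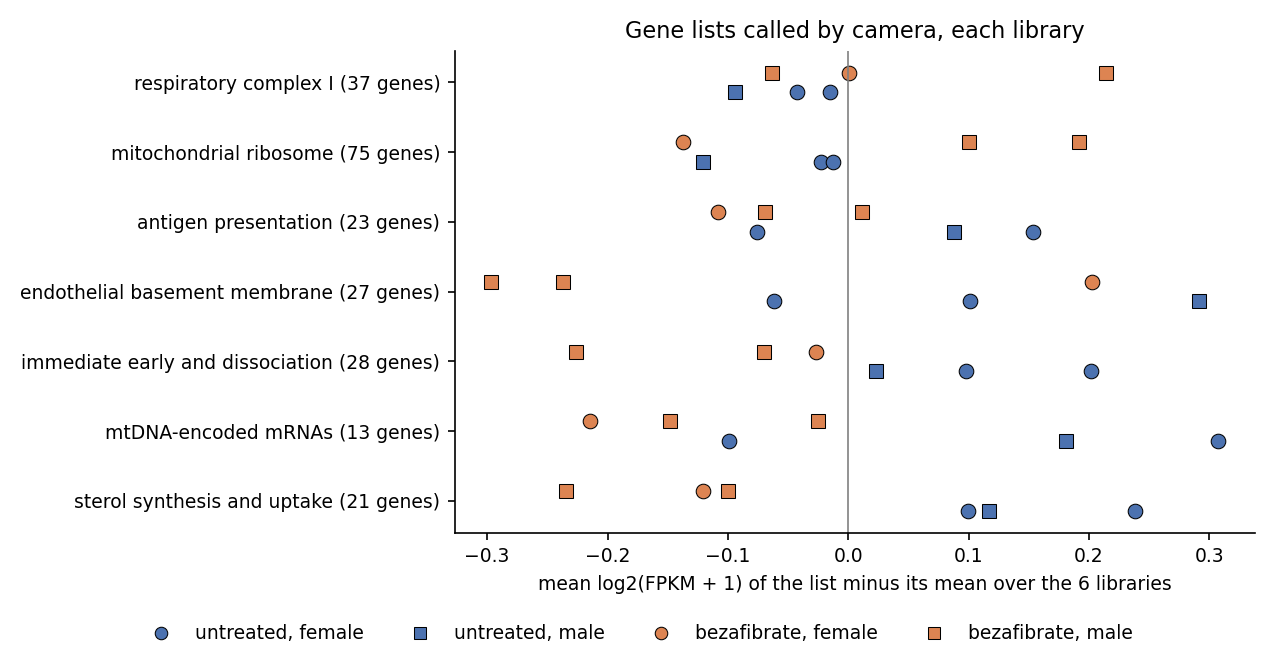
Mean log2(FPKM + 1) of each of the 7 lists called with camera, in each library, minus the mean over the 6 libraries (horizontal axis), by treatment (colour) and sex (symbol). The bezafibrate libraries lie apart from the untreated ones for the sterol and immediate early lists, and overlap them for the other 5.

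Basement membrane genes were lower, with a median of -0.21 and 26 of 27 below 0 (camera adjusted p = 2.94e-04, and adjusted p = 0.657 with an estimated correlation). The protease gene Adamts1 had 380 ± 19.3 FPKM in untreated and 252 ± 72.4 in bezafibrate libraries, and the laminin chain Lamc1 36.5 ± 0.560 and 31.5 ± 1.92. The list mean was 5.71 in untreated M_1 and 5.62 in bezafibrate F_1, the libraries that stood apart, against 5.36 and 5.52 in the other untreated and 5.18 and 5.12 in the other bezafibrate libraries. The median was -0.12 without untreated M_1 (adjusted p = 0.0520) and without bezafibrate M_2 (0.105). It fell to -0.015 (adjusted p = 0.852) with the composition ratio of the libraries as a covariate, a fit chosen after the data were seen. The call held in 20 of 24 alternative fits, and the replicate block was the other that ended it. Antigen presentation genes were lower at a median of -0.13 with 19 of 23 below 0 (camera adjusted p = 0.0426, and adjusted p = 0.657 with an estimated correlation), Calr having 152.5 ± 3.77 and 127 ± 5.60 FPKM. This call held in 15 of 24 alternative fits. It ended without untreated F_1 (-0.07, adjusted p = 0.359), untreated M_1 (-0.09, 0.102), bezafibrate F_1 (-0.10, 0.362) or bezafibrate M_1 (-0.12, 0.0972), and without both untreated M_1 and bezafibrate F_1 (-0.04, 0.507). It also ended after rescaling to TPM (-0.014, adjusted p = 0.217), under quantile scaling (-0.06, 0.547), with array weights (-0.04, 0.388) and at an FPKM of at least 5 (-0.13, 0.188).

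Barrier genes were not called as groups. Junction genes had a median of -0.11 with 21 of 25 below 0 (camera adjusted p = 0.173), and Cldn5 had 1183 ± 189.6 and 921 ± 246 FPKM. Transporters had a median of -0.05 (33 genes, adjusted p = 0.293), with Slc2a1 at 4447 ± 1297 and 3815 ± 1364, Abcb1a at 456.5 ± 70.1 and 423.5 ± 66.3, and Mfsd2a at 326 ± 101 and 269.9 ± 55.4. The log2 differences of Cdh5, Tjp1 and Ocln were -0.15 (SE 0.202), 0.08 (SE 0.180) and 0.16 (SE 0.151). Junction genes were called lower without untreated F_1 (-0.18, adjusted p = 0.0460) and without bezafibrate F_1 (-0.17, 0.0277). In the caveolae list (median 0.03, adjusted p = 0.442), Ackr1 was the 1 gene called when adjusted over the list alone, at 1.65 ± 0.295 and 3.77 ± 1.03 FPKM, with 25.7% of its exon bases shared with Cadm3. Ackr1 is also in the larger leukocyte adhesion and venous lists, where it was not called when adjusted over the list alone. In the Wnt list (median -0.03, though the test pointed up, adjusted p = 0.974), Axin2 was the 1 gene so called. Plvap, of endothelial fenestrae, had 41.8 ± 19.1 and 41.7 ± 13.1 FPKM.

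Further lists without a call were leukocyte adhesion (median -0.05, adjusted p = 0.567; Icam1 -0.41, Vcam1 0.21), interferon response (-0.05, 0.779), the stress responses (-0.07, 0.384), antioxidant response (-0.07, 0.293), glycolysis (-0.07, 0.175), angiogenesis (-0.18, 0.0583) and cell cycle (-0.03, 0.896). Angiogenesis genes were called lower in 6 of 24 alternative fits, with the lowest adjusted p, 0.00170, without both untreated M_1 and bezafibrate F_1. Leukocyte adhesion was called in 2 of them, interferon response in 1 and antioxidant response in 1. The 22q11.2 interval, hemizygous in all libraries, had a median of 0.05 over 14 measured genes (0.541), and of -0.07 to 0.22 with a library left out. The cytosolic ribosome stood at -0.06 (0.312), and the arterial, capillary and venous lists at -0.01 (0.384), -0.16 (0.218) and 0.13 (0.258). In alternative fits the 22q11.2 interval was called in 2, the cytosolic ribosome lower in 3 and higher in 2, the arterial list in 2 and the venous list in 1. Single values in these lists included Hmox1, the heme-degrading enzyme, at 5.69 ± 0.0920 and 9.74 ± 2.63 FPKM and the Notch ligand Jag1 at 14.5 ± 0.649 and 19.9 ± 2.12.

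Lists of cell type markers, endothelium among them, were also called at the preset correlation. Of 9 cell type lists, 5 were called with camera, and none with an estimated correlation (smallest adjusted p = 0.575) or by fry (0.725). Oligodendrocyte markers were lower at a median of -0.19 with 10 of 12 below 0 (adjusted p = 0.00241, 0.575 with an estimated correlation), Mobp having 6.36 ± 0.695 and 4.28 ± 0.428 FPKM. Endothelium (-0.15, 0.0149), pericyte (-0.23, 0.0290) and astrocyte markers (-0.18, 0.0290) were lower, each at an adjusted p = 0.575 with an estimated correlation. Ependymal and choroid plexus markers were higher at 0.24 with 12 of 13 above 0 (0.00241, and 0.575 with an estimated correlation). Ttr, the choroid plexus transthyretin gene, had 371 ± 19.9 and 619 ± 269.9 FPKM, and Clic6 1.96 ± 0.200 and 3.40 ± 1.17. Smooth muscle (0.01, 0.476), oligodendrocyte precursor (-0.22, 0.234), microglia (-0.09, 0.234) and erythrocyte markers (-0.07, 0.966) were not called, though microglia were in 3 of 23 alternative fits and erythrocytes lower in 1 and higher in 1.

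Each cell type call ended when certain single libraries were left out. Of 24 alternative fits, oligodendrocyte markers were called in 22, pericyte and astrocyte markers in 16 each and endothelium markers in 14, and choroid plexus markers in 19 of 23. Without untreated F_1 the oligodendrocyte median was -0.10 (adjusted p = 0.141), the pericyte median -0.15 (0.482) and the astrocyte median -0.13 (0.401). Without bezafibrate M_2 the choroid plexus median was 0.06 (0.281) and the endothelium median -0.10 (0.284), and without untreated F_2 they were 0.19 and -0.17 (0.0540 each). Endothelium calls also ended without untreated M_1 (-0.12, 0.0756) or bezafibrate M_1 (-0.14, 0.0520), astrocyte calls without untreated M_1 (-0.20, 0.188) or bezafibrate F_1 (-0.02, 0.926), and pericyte calls without untreated F_2 (-0.09, 0.470), bezafibrate F_1 (-0.25, 0.0759) or bezafibrate M_1 (-0.08, 0.229). Endothelium markers changed sign under quantile scaling (0.0038). With the composition ratio as a covariate the endothelium median was -0.059 (adjusted p = 0.591) and the choroid plexus median 0.17 (0.591). With sex as a covariate the pericyte median was -0.089 (adjusted p = 0.498) and the endothelium median -0.14 (0.0711).

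Sex separated the libraries by sex-linked genes. Ddx3y, on the Y chromosome, had 32.5 FPKM in untreated M_1 and 22.1 and 24.8 in bezafibrate M_1 and M_2, and 0 reads in the 3 female libraries, at least 2545-fold higher against a floor of 3 reads over the females (limma adjusted p = 6.67e-04). Eif2s3y had 7.13, 9.98 and 7.75 FPKM in males, at least 649-fold higher (adjusted p = 0.00575). Xist, the RNA that silences an X chromosome, had 11.9, 13.2 and 12.1 FPKM in females and 0 in males, at least 4332-fold higher in females (adjusted p = 9.87e-04). These were the 3 calls, matching the labelled sexes, with 331 genes at an unadjusted p under 0.05 where 564 would be counted by chance. Uty, also Y-linked, had 2.67, 2.28 and 2.19 FPKM in males and 0 in females (adjusted p = 0.209). The other genes of smallest p, Gm23802, Gm12941, Gm42778, AC121151.1, Snord72 and Gm13123, had adjusted p of 0.550 to 0.603. Among autosomal protein-coding genes limma called 0. The count of calls was 1, Xist, without bezafibrate M_1 or without bezafibrate M_2, where the Y-linked genes no longer met the filter of 3 libraries.

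The effect of bezafibrate was then compared between the sexes by the interaction term, which is negative where the male difference lay below the female difference. It was called for 75 genes, 49 lower and 26 higher, 60 of them protein-coding, with a smallest adjusted p of 0.0468. At an unadjusted p under 0.05 there were 2398 genes, against 564 by chance. The largest statistics belonged to Litaf (-3.90, SE 0.269), an endosomal membrane protein gene, Ramp3 (-3.91, SE 0.343), a partner of the calcitonin-like receptor, and Lrrc32 (-2.65, SE 0.246), a docking receptor for latent TGF-beta. Litaf had 40.4, 46.5 and 138 FPKM in untreated F_1, F_2 and M_1 and 74.9, 14.1 and 15.8 in bezafibrate F_1, M_1 and M_2. Ramp3 had 19.2, 17.5 and 82.3 against 35.2, 7.80 and 11.3, and Lrrc32 46.4, 44.4 and 92.9 against 60.2, 18.1 and 19.4. Trpv4 (-2.61), Smad6 (-2.78), Itga3 (-2.96), Wnt11 (-4.48), Cmpk2 (2.21) and Gbp7 (2.12) were also called.

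By list, the interaction was called for 5 pathway lists with camera. Interferon response (median 0.76, adjusted p = 2.27e-07) and mitochondrial ribosome genes (0.41, 4.65e-04) lay above other genes. Basement membrane (-0.70, 3.63e-04), cytosolic ribosome (-0.33, 5.55e-04) and leukocyte adhesion genes (-0.48, 0.00151) lay below. Each had an adjusted p = 0.987 with an estimated correlation. Pericyte markers were the 1 cell type list called (0.62, 0.00848, and adjusted p = 0.876 with an estimated correlation). The untreated male and the bezafibrate female cells of this design each held the single library that stood apart on the first principal component, M_1 and F_1. Under quantile scaling 1 gene, Litaf, was called, and by eBayes without a trend 0. Rescaling to TPM moved the median interaction term of all genes to 0.32 and called 132 genes higher and 90 lower.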

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

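The tests of endothelial markers, of the dissociation list, of the size of the terms under quantile scaling and of other ways to fill the 4 cells were chosen after the interaction was seen, and the count of calls by scaling before. The interaction of treatment with sex was picked out because its term, which tests the difference itself, was called. A difference between the sexes is not shown by it: the untreated male and bezafibrate female cells hold 1 library each, the model leaves 2 residual degrees of freedom, and eBayes without a trend called 0 genes. The term was called for 75 genes, led by Litaf (-3.90), Ramp3 (-3.91) and Lrrc32 (-2.65). Of the 45 ways to place the 6 libraries in 4 cells of these sizes, 1 gave as many calls, the real one, and the highest other gave 2. Chance is not excluded by this, since 3 of the 45 leave untreated M_1 and bezafibrate F_1 alone, a share of 0.0667. The other placements that do so had 1929 and 2040 genes at an unadjusted p under 0.05 and called 0, against 2398 for the real one, which points to a structure of the samples.

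What drives this pattern was weighed as follows. If untreated M_1 and bezafibrate F_1 held fewer endothelial cells, endothelial markers would be lower there. Their median term was -0.37 (20 markers, 95% bootstrap interval -0.70 to -0.11), which argues against it on the FPKM scale only. Camera did not call these markers for the interaction (adjusted p = 0.0838, and 0.876 with an estimated correlation). Rescaling to TPM moved the median term of all genes from -0.01 to 0.32, so the sign of the marker term may depend on scaling, which was not tested. A stronger dissociation response in them would give the list of immediate early genes a negative term. The median term of that list was 0.0056 (95% bootstrap interval -0.20 to 0.12), so no such shift was seen. The genes called lower (median -2.62) were picked by their terms in the same fit, so they set no size for the list to reach. A smaller dissociation response is therefore not excluded, and this explanation stays open. The authors' library scaling stays open as a reason for the number of calls. Median-of-ratios scaling gave 76 and quantile scaling 1, the latter meeting the bound set in advance. Under quantile scaling 2121 genes still lay at an unadjusted p under 0.05, against 2398, so the fall in calls does not decide it. The terms of the called genes changed little under quantile scaling. The median of the 49 genes called lower went from -2.62 to -2.32 (interquartile range -2.69 to -2.01). That of the 26 called higher went from 2.49 to 2.53 (2.23 to 2.91), while the median adjusted p rose to 0.0594. These genes were picked for large terms in the same fit, so this does not exclude scaling as a source of smaller terms. A difference between the sexes in the response to bezafibrate stays open and untested, since it cannot be told apart from whatever set those 2 libraries apart, each being alone in its cell.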

How the results depend on the processing

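Fits with voom, the composition ratio, the length trend, protein-coding genes alone and without untreated M_1 and bezafibrate F_1 were chosen after seeing the data. Of 2347 named gene values under alternatives, 2335 kept their direction and side of the threshold, 4 gained and 8 lost a call and 0 reversed; 47 changed sign within 1 SE of 0 with no call in either fit and are counted as kept. Of 1009 list values, 897 kept their side of the threshold, 24 gained a call, 82 lost one and 6 reversed. A list with no call in either fit was counted as kept even where its direction changed. The median of the uncalled PPAR-alpha targets, for example, ran from -0.09 to 0.05. With a median SE of 0.191, changes of log2 0.5 in single genes are mostly below what 3 pools a group can call. Where few genes change, larger changes can be missed too. The top-ranked gene would have needed a log2 change of 2.2 at that SE. The planned count model was not run because the table holds FPKM.

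The treatment count of 1 gene was 0 among autosomal protein-coding genes, among protein-coding genes alone, by limma-voom and without untreated M_1 and bezafibrate F_1, and 2 by eBayes without a trend (Gm27616 and Gm11626). Leaving out 1 library gave 0 to 3 genes. The 7 lists called became 4 to 9 with a library left out, 0 with an estimated correlation and 0 by fry. For sex, 0 autosomal protein-coding genes were called and 1 to 4 genes with a library left out. The protein-coding sets leave out Gm27616, a predicted microRNA, and the autosomal set leaves out the sex-linked genes called for sex. Without a bezafibrate library Gm27616 did not meet the expression filter. The cause of the other changes was not tested, beyond the smaller sets of genes and libraries in these fits.

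The 75 interaction genes became 131 with a pseudocount of 5, 478 with no filter, 571 at an FPKM of at least 5, 222 after rescaling to TPM, 1 under quantile scaling, 833 among autosomal protein-coding genes, 0 without a trend, 383 with robust eBayes, 861 by limma-voom, 233 with the length trend removed and 804 among protein-coding genes alone. The adjusted p of the 75 genes lay between 0.0468 and 0.05, so small shifts can end many calls. What raised the count in other fits was not tested.

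Reversed medians were the cytosolic ribosome under quantile scaling (0.063, adjusted p = 0.0235) and without bezafibrate M_1 (0.062, 0.00165, range with a library left out -0.14 to 0.062), endothelium under quantile scaling (0.0038), astrocyte with array weights (0.033) and without untreated M_1 and bezafibrate F_1 (0.0072), and erythrocyte without untreated F_1 (0.40, 0.0217, range with a library left out -0.56 to 0.40). The cause was not tested.

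With the replicate block, 0 genes and 8 lists were called, and complex I (0.04, adjusted p = 0.574), the mitochondrial ribosome (0.08, 0.252) and basement membrane (-0.16, 0.144) were not among them. Untreated F_2 and bezafibrate M_2 had no partner, so this fit took the treatment difference from the F_1 and M_1 libraries alone. The names share sex and a number, with no sign of pairing: deviations of F_1 with F_1 and M_1 with M_1 correlated at -0.36 and -0.30 across genes.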

Other observations

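Values of pituitary hormone genes and the tests of glial markers, gene length, composition and sex were chosen after results were seen, and the splits of treatment and sex before. RNAs of the anterior pituitary were present in some libraries of this endothelial sort. Gh, growth hormone (ENSMUSG00000020713, chromosome 11, 106300271 to 106301865), had 113 and 11.3 FPKM in untreated F_1 and F_2 and 230.1 in bezafibrate M_2 (1958, 174 and 3728 reads), and 0 reads in untreated M_1, bezafibrate F_1 and bezafibrate M_1. Prl, prolactin, had 7.42, 13.6 and 15.7 FPKM in the same 3 libraries and 0 in the others. Pomc had 5.85, 6.05 and 4.00 FPKM in untreated F_1, F_2 and M_1 and 2.70, 3.18 and 10.1 in bezafibrate F_1, M_1 and M_2. Cga was read in the same 3 libraries as Gh, and Fshb and Ghrhr had 0 reads throughout. Other pituitary genes did not follow Gh: Lhb had 23 reads in bezafibrate M_1, Tshb 11 in untreated M_1 and Pou1f1 18 in bezafibrate F_1. Alas2, of heme synthesis in red cells, ran from 0.0196 FPKM in bezafibrate M_1 to 2.02 in bezafibrate M_2.

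Other splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For treatment genes, 3 of 10 splits called at least as many genes as the real 1, and the highest other called 4. For treatment lists, 3 of 10 called at least the real 7. The other splits called 1 to 8 lists, so this number of calls is not particular to treatment. For sex, 1 of 9 splits gave as many as the real 3 genes, and the highest other gave 1. The split of untreated F_1, bezafibrate M_1 and bezafibrate M_2 from the rest had 2132 genes at an unadjusted p under 0.05, against 472 for treatment, which points to a structure of the samples along the first principal component, although it called 0 genes.

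The lower sterol genes with bezafibrate were weighed against technical explanations. With the composition ratio as a covariate the sterol median was -0.31 (camera adjusted p = 1.59e-06), and with sex as a covariate -0.34 (8.56e-06), which argue against either as the whole cause. Fewer glial cells in the bezafibrate libraries stay open: 26 oligodendrocyte and astrocyte markers had a median of -0.19, and their median minus that of the sterol genes was 0.17, with a 95% bootstrap interval of -0.08 to 0.26 that includes 0. The CD31-positive gate would remove intact glial cells, yet Mbp had 13.4 FPKM in untreated libraries; 2 of the markers, Aldoc and Clu, are also in other lists. An effect of bezafibrate on sterol synthesis in the endothelium stays open as a hypothesis, untested beyond the list itself.

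The higher complex I and mitochondrial ribosome genes were also weighed. With each library's gene length trend removed the medians were 0.084 and 0.088, and both calls held, which argues against length bias as the cause. With the composition ratio as a covariate they moved from 0.092 to 0.019 for complex I (interquartile range -0.01 to 0.19 before and -0.06 to 0.20 after) and from 0.089 to 0.036 for the ribosome (-0.07 to 0.25 and -0.15 to 0.15), and both calls ended because the medians fell toward 0. The covariate also ended the calls of basement membrane (-0.21 to -0.015, interquartile range -0.27 to -0.13 before and -0.16 to 0.09 after), endothelium (-0.15 to -0.059, -0.24 to -0.08 and -0.20 to 0.12) and choroid plexus (0.24 to 0.17, 0.20 to 0.54 and -0.14 to 0.23). Library composition is a candidate explanation for the complex I, ribosome, basement membrane and endothelium lists, although the ratio is itself computed from the expression values. The choroid plexus median kept most of its size, so the end of its call says less about composition. With sex as a covariate complex I stayed called (0.075, adjusted p = 0.0347), which argues against the unbalanced sexes as its whole cause, while the ribosome median did not shrink (0.106, interquartile range -0.10 to 0.21) and its call ended (0.0631) as the median SE of all genes rose from 0.191 to 0.206, which gives no support to sex without excluding it; an effect of bezafibrate stays open and was not otherwise tested.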
